A study of Mus musculus with 4 samples.

How the data were processed

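RNA-seq libraries of hair follicle stem cells from C57BL/6 mice in anagen were compared between a normal diet and a high-fat diet given for 4 months, with 2 libraries per diet, grouped by the diet that each sample's labels give. Per the labels' protocols, total RNA was purified with silica columns and libraries were made with standard Illumina protocols. The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.9.1 and HISAT2 2.0.1, without saying what each did. The counting program, its handling of strand and of reads that fit several places, the annotation and the genome build are not given in the sources used here.

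The authors deposited 1 table with a raw count and an FPKM value (fragments scaled by exonic length and library total) for each gene and library, and with gene symbols, coordinates and exonic sizes. The deposited counts were whole numbers that summed to between 8590570 and 9940848 per library. All 221604 deposited FPKM values equalled the count divided by exonic size and by the column's total count, within 0.0051 FPKM, so the FPKM carry no scaling beyond the total. Coordinates are those of the table. Of its 55401 gene identifiers 55141 occur in a GENCODE annotation of mouse build GRCm38, and 54821 of those (99.4%) have the same chromosome, start and end there, so positions are given on GRCm38. A few features took a large share of the counts. The ribosomal RNA-like gene Gm23935 took 8.31% and 9.89% of counts with the normal diet and 9.12% and 8.48% with the high-fat diet, and the 10 most abundant features took between 22.8% and 27.8%. Because the molecules carried no identifiers, the floor of 3 counts per library covers counting error only.

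Differential expression was tested on the deposited counts in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, using TMM scaling, a prior variance that follows abundance, and the default filter for expression by group. That filter asks for a CPM worth about 10 counts in at least 2 libraries and for 15 counts in total, and kept 14479 genes. A gene could therefore pass through the libraries of 1 diet alone. TMM factors lay between 0.965 and 1.04. The plan written before the data were examined assumed FPKM and limma, with edgeR in its place if counts were present, as they were, and limma 3.58.1 on log2(FPKM + 1) became an alternative. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error of a log2 fold change is its size divided by the square root of the test's F value. CPM are scaled by TMM, and SDs are over the 2 libraries of a diet. The common biological coefficient of variation was 20.3%. The labels give both diets the same replicate numbers but no statement that these pair the libraries, so the fit had no replicate term.

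Before the data were examined, 35 gene lists were written from general knowledge of skin, follicle, metabolism, signalling and other cell types of skin, and the 32 with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Lists share members, so they are not independent. Examples are Gli1 in the hedgehog and upper follicle lists and Scd1 in the sebaceous and the sterol and fatty acid synthesis lists. Of 32 measured bulge markers 19 occur in another list. Named genes were chosen by a rule written at the same time, with 3 parts. It took the 12 largest rises and falls among called genes with a mean FPKM of at least 1 and no overlap between the diets, leaving out unnamed gene models, the up to 4 genes of each list with the smallest p, and 22 genes of prior interest whatever their values. For brevity many genes of the second part are given only as counts, and a few genes that the rule names are not reported here. Gata6 and Krtdap, and in the closing section Abca12, Evpl, Ppl, H2-Q7 and Hrnr, were added after their values were seen, to name the members behind a count.

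The fits were tested on simulated counts with the means and library sizes of the 14479 genes and with 200 changed genes. Dispersions were those of the trend with abundance, not of each gene. For this comparison edgeR recovered 50% of genes changed 2-fold and 84% of those changed 4-fold, with 4 unchanged genes among 138 calls. DESeq2 1.42.0 recovered 44% and 80%, and limma on log2(FPKM + 1) 9% and 59%. Alternatives planned before the data were examined were other count filters, scalings, pseudocounts of 0.1 and 0.01, priors, tools and thresholds, a replicate block, and leaving out each library in turn, where the lone library is assumed to vary like the pair of the other diet. Removal of a smooth trend (span 0.3) on exonic length or on GC content, removal of ribosomal, mitochondrial and small RNAs, and edgeR with a filter of mean FPKM at least 1 were chosen after seeing the data. Biological process terms listed in the table, with 10 to 500 tested genes, were tested among called genes by a one-sided Fisher's exact test against the 10160 tested genes that have a term, adjusted over 1247 terms for each direction. Figures were drawn with matplotlib.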

Results

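Gene expression was measured by RNA-seq in hair follicle stem cells of C57BL/6 mice, taken in anagen, the growth phase of the hair cycle. The stem cells of the follicle reside in the bulge, a niche in the lower permanent part of the follicle, and give rise to new hair in each cycle. Mice had received a normal diet, or a high-fat diet for 4 months, and each diet was represented by 2 libraries. The deposited table held 55401 genes, of which 24790 had a count in at least 1 library. Total counts were 9940848 and 9366856 in the normal diet libraries and 8734246 and 8590570 in the high-fat diet libraries. At this depth 3 counts corresponded to between 0.291 and 0.359 CPM (counts scaled to the TMM-adjusted library size). The labels did not state how the cells were isolated or whether the 2 libraries of a diet came from separate mice. P-values therefore measure only the spread between these libraries, which may be technical. Within a diet the libraries differed by more than sampling noise. The ratio of chi-square to its degrees of freedom was 13.9 for the normal diet pair and 6.53 for the high-fat diet pair. Between the diets this ratio was 15.3 and 17.1 for the second normal diet library against the first and second high-fat diet libraries. For the first normal diet library it was 25.5 and 24.98. By this ratio the normal diet libraries differed from each other nearly as much as the second differed from the first high-fat diet library.

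The comparison asked which transcripts of the stem cells differed between the diets. With the high-fat diet, gene lists of basal and suprabasal epidermis, of the upper follicle and of the mitochondrial genome were shifted up. The summed expression of the upper follicle list did not rise. Lists of the cell cycle and of the Sonic hedgehog pathway were shifted down. These shifts of whole lists passed camera with its preset correlation and did not pass with an estimated correlation (adjusted p = 0.44 for each). Among single genes, 162 were higher and 33 lower of the 14479 genes tested (edgeR quasi-likelihood test, adjusted p under 0.05, 2 libraries against 2). The values of the 2 diets did not overlap for any of these 195 genes, a separation seen in 44.6% of all genes tested, where chance gives 33.3%. Scaling the libraries to equal sums of TPM (transcript abundance relative to length) gave 90 higher and 3 lower genes, 88 and 3 of them among those called here, so that 96.8% of the calls were higher against 83.1% with the scaling used here. The calls depended on the number of libraries. Without the first normal diet library edgeR called 0 genes, with 1488 at an unadjusted p under 0.05 against 1922 in all 4 libraries. Without the second normal diet library it called 3 higher and 0 lower genes, with 2403 at an unadjusted p under 0.05. Without the first or the second high-fat diet library it called 81 and 56 higher genes and 2 lower genes each time. DESeq2 called 275 higher and 119 lower genes, whereas limma on log2(FPKM + 1) called 1 higher and 0 lower, with 1793 genes at an unadjusted p under 0.05.

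**Figure D1:**
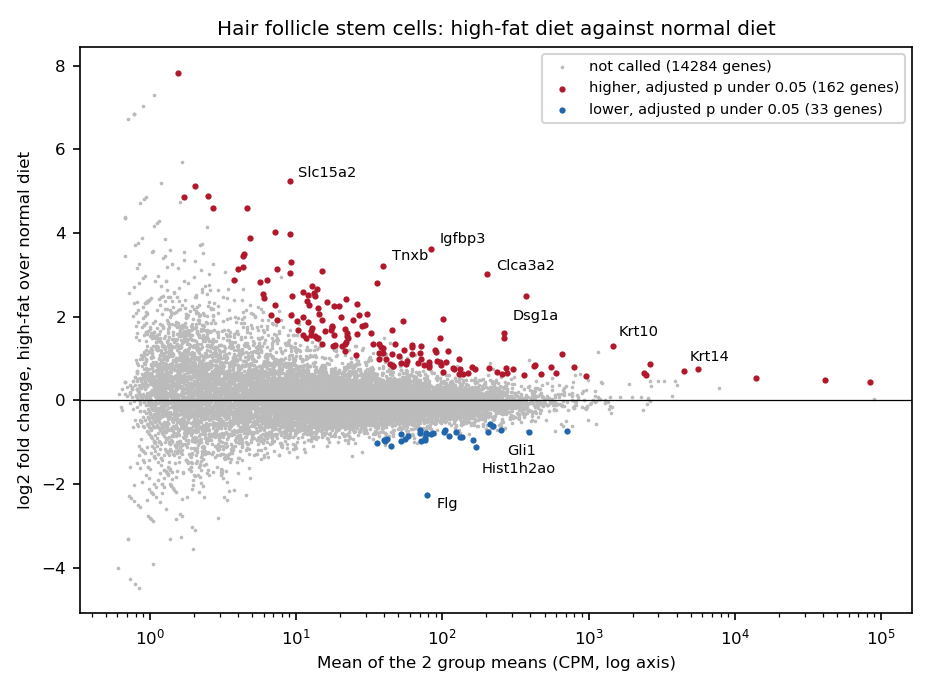
Mean expression in CPM on a log axis against the log2 fold change of high-fat over normal diet, 1 point per tested gene, with 2 libraries per diet. The 162 genes called higher (red) and the 33 called lower (blue) at an adjusted p under 0.05 (edgeR) are coloured, and called genes with a log2 fold change above 1 outnumber those below -1.

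The chloride channel accessory gene Clca3a2 had the smallest adjusted p of the named genes (chromosome 3, positions 144796559 to 144819494, minus strand). It rose 8.09-fold, from 44.5 ± 3.28 to 360 ± 12.3 CPM (mean ± SD, n = 2 per diet), a log2 fold change of 3.02 with a standard error of 0.14 (edgeR adjusted p = 1.45e-06). Its neighbour Clca3a1 rose by a log2 fold change of 3.19 from a mean of 0.848 CPM (2.43 without the second high-fat diet library), and since both genes are close relatives, reads shared between them leave their separate values uncertain. Tnxb, which encodes the matrix protein tenascin X (chromosome 17, positions 34660457 to 34719815), rose from 7.68 ± 0.692 to 71.4 ± 5.23 CPM (SD, n = 2), a 9.30-fold change. Igfbp3, a secreted protein that binds insulin-like growth factors (chromosome 11, positions 7206086 to 7213923), rose 12.2-fold from 12.7 ± 9.29 to 154 ± 0.711 CPM (SD, n = 2). Its normal diet libraries stood at 6.12 and 19.3 CPM, and its log2 fold change of 3.61 was 4.65 without the second of these libraries. Without the first it was smaller and the call was lost (adjusted p = 0.087). The other genes among the 12 largest rises started from means under 2 CPM with the normal diet. Slc15a2, a proton-coupled peptide transporter, had 4 and 5 counts against 72 and 223. The others were the cytokine receptor chains Il20ra and Il12rb2, the metalloproteinase Mmp28, the peptidoglycan recognition protein Pglyrp4, Skint7, Slc24a3 and Cpxm2. Il20ra had 0 and 16 counts with the normal diet and Mmp28 1 and 20, and without the first normal diet library their log2 fold changes of 4.03 and 3.99 were 3.01 and 3.04. That of Slc15a2 ranged from 4.20 without the second high-fat diet library to 5.84 without the first. Log2 fold changes of these genes lay between 3.04 for Il12rb2 and 5.24 for Slc15a2, with standard errors between 0.40 for Il12rb2 and 0.80 for Il20ra. Skint7 belongs to a family of similar genes on chromosome 4, so its separate value is uncertain.

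Of 36 measured suprabasal epidermal differentiation genes, 6 were higher and 1 was lower over all genes tested, and 22 were higher and 3 lower when adjusted over the list alone. Krt10, the keratin of spinous cells (chromosome 11, positions 99385254 to 99389364), rose 2.45-fold from 853 ± 431 to 2086 ± 397 CPM (SD, n = 2; edgeR adjusted p = 0.040). Its normal diet libraries stood at 548 and 1158 CPM, and its log2 fold change of 1.29 was 0.85 without the first normal diet library and 1.92 without the second. Its call was lost in both cases (adjusted p = 0.464 and 0.139) and without the second high-fat diet library (adjusted p = 0.078). Dsg1a, a desmosomal cadherin (chromosome 18, positions 20310811 to 20343350), rose 3.06-fold from 130 ± 11.5 to 397 ± 55.1 CPM (SD, n = 2), with an edgeR adjusted p of 2.99e-04. Krt77 rose 2.16-fold, Krtdap 2.14-fold and Ptgs1, a cyclooxygenase, 3.08-fold, and Krt2 had 2 and 1 counts with the normal diet against 50 and 31. Krt1 and Ivl, which encodes the envelope protein involucrin, had log2 fold changes of 1.17 ± 0.41 and 0.89 ± 0.33 (SE) that did not pass the test, with edgeR adjusted p of 0.236 and 0.263. Flg, the filaggrin gene of the granular layer (chromosome 3, positions 93273523 to 93293686), went the other way and fell from 131 ± 107 to 27.1 ± 9.97 CPM (SD, n = 2; edgeR adjusted p = 0.041). The normal diet libraries stood at 55.2 and 207 CPM for Flg, and its log2 fold change of -2.27 was -2.93 without the first and -1.03 without the second. The median log2 fold change of the list was 0.71, and camera placed it above the other genes (adjusted p = 3.79e-15; adjusted p = 0.44 with an estimated correlation). The normal diet libraries differed in this list too, with summed values of 2308 and 4318 CPM against 5814 and 7220 CPM with the high-fat diet, and the median was 0.49 without the first normal diet library and 1.16 without the second.

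Of 20 basal epidermal genes, 4 were higher and 0 lower over all genes, and 9 were higher when adjusted over the list alone. The median log2 fold change was 0.44 (camera adjusted p = 4.69e-11; adjusted p = 0.44 with an estimated correlation). Krt14, the main keratin of basal cells, rose 1.62-fold from 3412 ± 596 to 5526 ± 738 CPM (SD, n = 2). Ly6d rose 3.73-fold and Fgfbp1 3.35-fold, and the log2 fold change of Ly6d was larger, at 2.53, without the second normal diet library. The median of this list was 0.75 without the second normal diet library and 0.29 without the first high-fat diet library. Among 18 genes of the infundibulum, isthmus and junctional zone, the parts of the follicle above the bulge, 4 were higher and 1 was lower, and 8 were higher and 1 lower when adjusted over the list alone. The median was 0.54 (camera adjusted p = 7.30e-05; adjusted p = 0.44 with an estimated correlation). Log2 fold changes were positive for 13 of these genes and negative for 5. Summed over the list, expression was 4973 ± 525 CPM with the normal diet and 4834 ± 336 CPM with the high-fat diet (SD, n = 2). That difference lay within the spread between libraries. Cst6, a cysteine protease inhibitor, rose 2.83-fold, Defb6, a beta-defensin, 2.21-fold, Krt79 1.57-fold and the transcription factor Gata6 3.78-fold. The gene lower in this list was Gli1, which the hedgehog list also holds. Wound and stress keratinocyte genes had a median of 0.89 over 14 genes, of which 6 exceeded a mean of 5 CPM. Camera called the list (adjusted p = 3.66e-04; adjusted p = 0.44 with an estimated correlation). Of the 14 genes 1 was higher over all genes, the alarmin Il33, and 2 were higher when adjusted over the list alone. The log2 fold change of 1.99 for Il33 was 1.37 without the first normal diet library and 3.09 without the second. Without the first normal diet library the median of the stress list was 0.52 and the camera call was lost (adjusted p = 0.064).

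**Figure D2:**
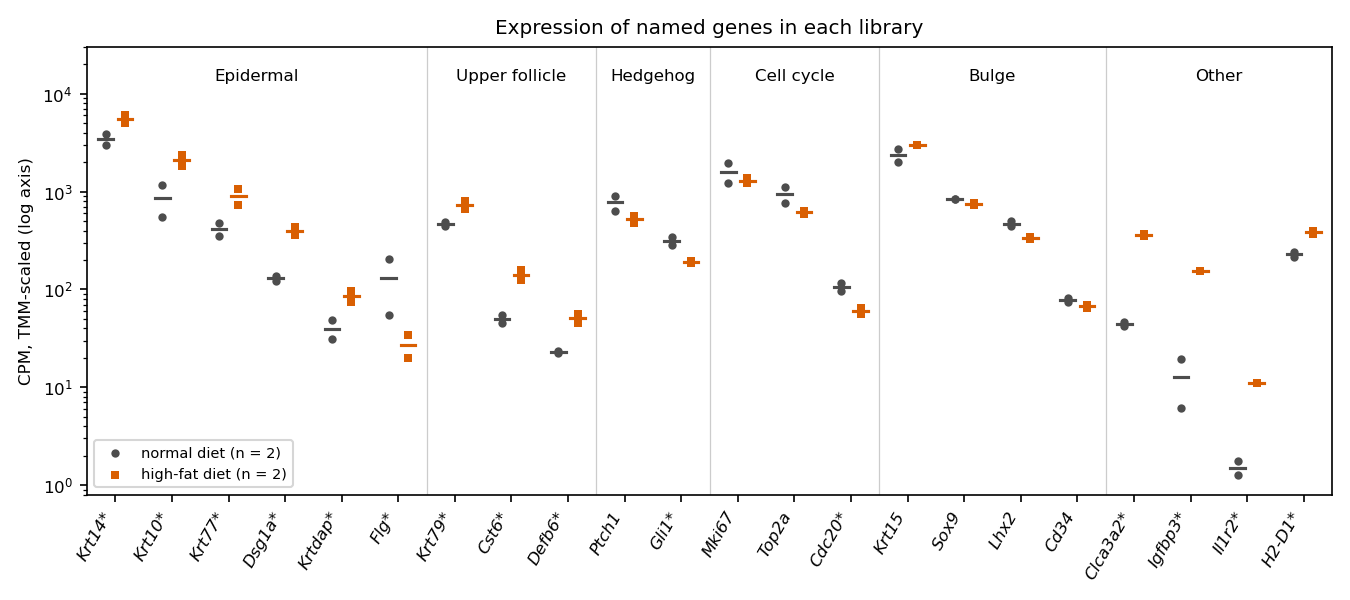
CPM on a log axis of named genes in each of the 4 libraries, with normal diet in grey and high-fat diet in orange. Points are libraries, short bars are the means of 2 libraries, and an asterisk marks an edgeR adjusted p under 0.05; Krt10, Dsg1a and Cst6 lie higher and Gli1 and Cdc20 lower with the high-fat diet.

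Markers of bulge stem cells were not called as a list. Of 32 measured genes, 0 passed over all genes tested at an adjusted p under 0.05 (edgeR), and 1 was higher and 2 were lower when adjusted over the list alone, with a median log2 fold change of -0.13 (camera adjusted p = 0.113). Sox9, Lgr5, Cd34 and Nfatc1 had log2 fold changes of -0.18 ± 0.11, -0.13 ± 0.12, -0.20 ± 0.15 and -0.27 ± 0.12 (SE). Lhx2 stood at 471 ± 35.5 CPM with the normal diet and 334 ± 7.57 CPM with the high-fat diet (SD, n = 2), which missed the threshold (edgeR adjusted p = 0.074). Krt15 and Col17a1, a collagen of the hemidesmosome, had positive log2 fold changes of 0.34 ± 0.14 and 0.46 ± 0.12 (SE) that did not pass either (edgeR adjusted p = 0.302 and 0.115). Hair germ and matrix progenitor markers had 0 of 18 genes called over all genes, and 3 higher and 3 lower when adjusted over the list alone (edgeR). Their median of -0.03 and mean of 0.31 differed in sign, and camera gave an upward direction without a call (adjusted p = 0.739).

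Cell cycle genes of the S and G2/M phases were lower, with negative log2 fold changes for 50 of 50 measured genes and a median of -0.51 (camera adjusted p = 5.03e-22; adjusted p = 0.44 with an estimated correlation). Over all genes tested 1 passed, Cdc20, an activator of the anaphase-promoting complex, which fell from 106 ± 14.5 to 60.3 ± 5.10 CPM (SD, n = 2; edgeR adjusted p = 0.033). Adjusted over the list alone, 37 were lower and 0 higher. Top2a and Mcm5 had log2 fold changes of -0.61 ± 0.16 and -0.61 ± 0.13 (SE), with edgeR adjusted p of 0.095 and 0.051, and Mki67 had one of -0.29 ± 0.18 (SE; adjusted p = 0.533). The normal diet libraries differed in this list, with summed values of 10643 and 7435 CPM against 6361 and 6747 CPM with the high-fat diet. Without the first normal diet library the median was -0.26, with 45 of 50 genes negative, and the log2 fold change of Mki67 was 0.09.

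Of 21 measured genes of the Sonic hedgehog pathway, which drives growth of the anagen follicle, 2 were lower and 0 higher over all genes, and 8 were lower when adjusted over the list alone. The median was -0.41 (camera adjusted p = 1.02e-05; adjusted p = 0.44 with an estimated correlation). Gli1, a transcriptional effector and target of the pathway (chromosome 10, positions 127329882 to 127341974), fell from 312 ± 39.3 to 190 ± 7.60 CPM (SD, n = 2), a log2 fold change of -0.72 with a standard error of 0.13 (edgeR adjusted p = 0.026). The receptor gene Ptch1 had a log2 fold change of -0.58 ± 0.16 (SE) that did not pass (edgeR adjusted p = 0.131). The ligand Shh was too low to test, with 0 counts in 3 libraries and 2 counts in the first high-fat diet library. Among the 12 largest falls were Flg and the histone genes Hist1h2ao, H4c12, H2bc11 and H2ac20. They also included the Wnt receptor Ror2, the transcriptional repressor Prdm1, the non-muscle myosin Myh10, Col27a1, Cdca2 and Mex3d. Apart from Flg, the log2 fold changes of these genes lay between -1.13 for Hist1h2ao and -0.92 for Cdca2. The histone genes have near-identical copies, so the value of each copy is uncertain.

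Mitochondrially encoded transcripts were higher, with positive log2 fold changes for 14 of 14 genes, 5 higher and 0 lower over all genes and 10 higher when adjusted over the list alone. The median was 0.49 (camera adjusted p = 6.83e-09; adjusted p = 0.44 with an estimated correlation). mt-Nd5, a complex I subunit, rose 1.57-fold and mt-Cytb, the cytochrome b gene, 1.52-fold. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 together took 10.9 ± 0.0847% of all counts with the normal diet and 14.0 ± 0.357% with the high-fat diet (SD, n = 2). The 18S-related ribosomal RNA CT010467.1 took 1.17 ± 0.0784% and 1.60 ± 0.143%. Of 44 nuclear-encoded oxidative phosphorylation genes 0 were called over all genes and 0 when adjusted over the list alone (edgeR; median -0.07, camera adjusted p = 0.073).

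Interleukin-1 and NF-kB genes had 2 of 32 higher and 0 lower over all genes and 3 higher when adjusted over the list alone (median 0.31, camera adjusted p = 2.70e-04; adjusted p = 0.44 with an estimated correlation). The 2 genes were both antagonists of interleukin-1, the decoy receptor Il1r2 and the receptor antagonist Il1rn, which rose 7.31-fold and 3.66-fold to 11.1 ± 0.129 and 19.1 ± 0.912 CPM (SD, n = 2). Nfkbia and the signalling receptor Il1r1 had log2 fold changes of 0.66 ± 0.20 and 0.10 ± 0.28 (SE) that did not pass (edgeR adjusted p = 0.179 and 0.932), and Il1b had 1 count in all 4 libraries together. The median of this list was 0.64 without the second normal diet library. Of 31 interferon-stimulated genes 3 were higher and 0 lower, and 4 were higher when adjusted over the list alone (median 0.27, camera adjusted p = 0.019; adjusted p = 0.44 with an estimated correlation). The members went both ways, with 19 positive and 12 negative log2 fold changes and a mean of 0.13. The 3 genes called over all genes were the class I histocompatibility genes H2-D1, which rose 1.67-fold from 229 ± 18.3 to 383 ± 16.6 CPM (SD, n = 2), and H2-K1, which rose 1.71-fold, and their partner B2m, which rose 1.57-fold. H2-D1 and H2-K1 are similar enough that shared reads leave their separate values uncertain. The interferon call was lost without the second normal diet library (adjusted p = 0.070) and without the first high-fat diet library (adjusted p = 0.068). Of 35 Wnt pathway genes 4 were higher and 0 lower, and 8 were higher and 1 lower when adjusted over the list alone (median 0.13, camera adjusted p = 0.019; adjusted p = 0.58 with an estimated correlation). They were the receptor gene Fzd10, which rose 5.90-fold, the ligand gene Wnt3, which rose 5.68-fold, Lrp4, which rose 2.28-fold, and Rspo3, with 1 count in each normal diet library against 33 and 23. The Wnt call was lost without the first normal diet library (adjusted p = 0.217) and without the first high-fat diet library (adjusted p = 0.094).

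Of the lipid gene lists, 1 was called. Of 36 sterol and fatty acid synthesis genes 0 passed over all genes (edgeR) and 2 were lower when adjusted over the list alone, and the list was shifted down (median -0.18, camera adjusted p = 0.0010; adjusted p = 0.44 with an estimated correlation). Scd1, a fatty acid desaturase, had a log2 fold change of -0.37 ± 0.15 (SE; edgeR adjusted p = 0.297). Of 23 fatty acid uptake and storage genes edgeR called 0 over all genes and 0 when adjusted over the list alone (median 0.04, camera adjusted p = 0.718). Of 31 fatty acid oxidation genes it called 0 over all genes and 1 higher when adjusted over the list alone (median 0.17, camera adjusted p = 0.059). Plin2, which coats lipid droplets, stood at 53.5 ± 5.04 and 50.8 ± 0.941 CPM (SD, n = 2) with the normal and the high-fat diet, and the fatty acid transporter Cd36 had 9 and 6 counts against 9 and 15, too few to test. Sebaceous gland genes had 2 of 24 higher, Acsbg1 and Elovl4, and 1 lower, Prdm1, with 3 higher and 4 lower when adjusted over the list alone (median -0.01, camera adjusted p = 0.923). Oxidative stress genes had 0 of 39 called over all genes and 0 over the list alone (edgeR; median 0.05, camera adjusted p = 0.430), and the antioxidant genes Nqo1 and Hmox1 had log2 fold changes of 0.27 ± 0.30 and -0.25 ± 0.67 (SE).

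Of the lists of other cell types, 2 were called. Macrophage, dendritic and Langerhans cell markers had a median log2 fold change of 0.77 over 12 genes, of which 4 exceeded a mean of 5 CPM. Of these 12 genes 0 were called over all genes or over the list alone (edgeR), while the list was shifted (camera adjusted p = 0.017; adjusted p = 0.44 with an estimated correlation). The most abundant of these, Cd74, stood at 18.2 ± 7.59 and 31.8 ± 1.04 CPM (SD, n = 2). This call was lost without the first normal diet library (median 0.30, adjusted p = 0.394) and without the second high-fat diet library (adjusted p = 0.097), and the median was 1.39 without the second normal diet library. Dermal fibroblast markers had a median of 0.53 over 21 genes, with 0 called over all genes or over the list alone (edgeR; camera adjusted p = 0.032; adjusted p = 0.44 with an estimated correlation), and the camera call was lost without either normal diet library (adjusted p = 0.064 and 0.077) and without the first high-fat diet library (adjusted p = 0.126). Of these 21 genes 13 exceeded a mean of 5 CPM, and their summed expression was 468 ± 24.9 CPM with the normal diet and 479 ± 27.0 CPM with the high-fat diet (SD, n = 2), a difference within the spread between libraries. T cell markers (median 1.08 over 11 genes, 3 of them above 5 CPM), endothelium and blood markers (median 0.69 over 10) and melanocyte, Schwann and Merkel cell markers (median -0.01 over 11) were not called (camera adjusted p = 0.059, 0.113 and 0.739), and edgeR called 0 of their genes over all genes and 0 when adjusted over the list alone. Lists of neutrophils and mast cells, adipocytes and muscle had 1, 3 and 4 measured genes and were not tested.

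**Figure D3:**
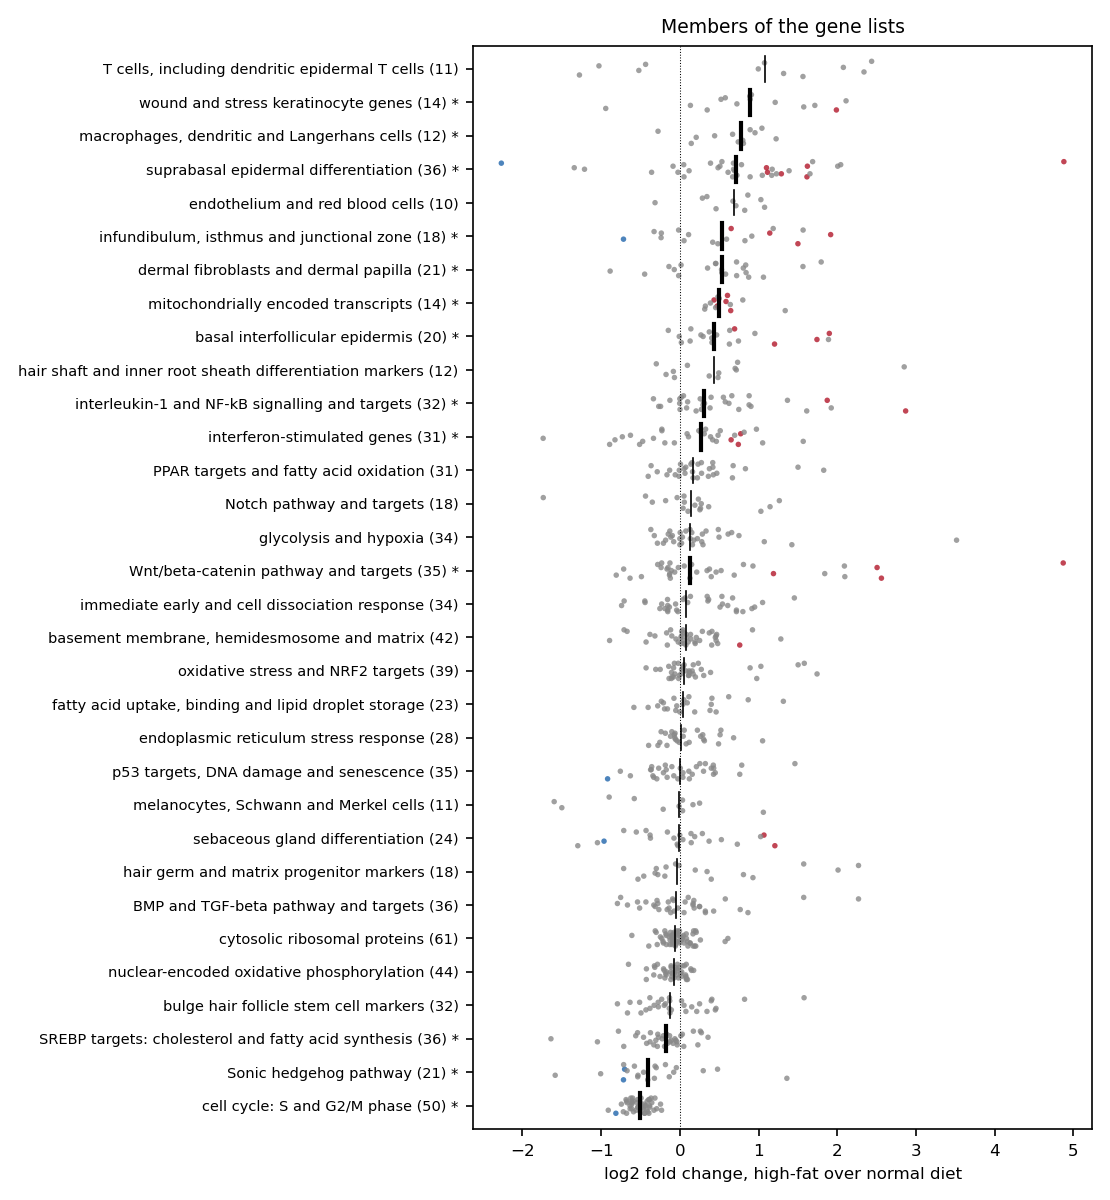
Log2 fold change of high-fat over normal diet for each measured member of the 32 tested lists (points; red higher and blue lower at an edgeR adjusted p under 0.05), with the number of measured genes in parentheses. Vertical bars are medians, thick with an asterisk for the 13 lists that camera called at an adjusted p under 0.05; the median was lowest for cell cycle genes at -0.51.

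The other lists were not called by camera. Their medians were 0.43 for hair shaft and inner root sheath genes (adjusted p = 0.070), 0.15 for Notch (adjusted p = 0.149), 0.13 for glycolysis and hypoxia (adjusted p = 0.067), 0.08 for basement membrane and matrix (adjusted p = 0.070) and 0.08 for immediate early genes (adjusted p = 0.085). They were 0.02 for endoplasmic reticulum stress (adjusted p = 0.756), 0.01 for p53 and DNA damage (adjusted p = 0.739), -0.05 for BMP and TGF-beta (adjusted p = 0.945) and -0.06 for cytosolic ribosomal proteins (adjusted p = 0.254). The mean was positive for BMP and TGF-beta at 0.07, as was the direction that camera gave, and camera gave a downward direction for p53 and DNA damage. Over all genes 1 gene of these 9 lists was called higher, Tnc, the matrix protein tenascin C, which rose 1.70-fold. Adjusted over the list alone, 4 genes were higher for glycolysis and hypoxia, 4 higher and 2 lower for basement membrane and matrix, and 3 higher and 2 lower for immediate early genes. In the same way 2 were higher and 2 lower for BMP and TGF-beta, 1 higher and 1 lower for p53 and DNA damage, 1 higher for Notch and 0 for the others (edgeR). Camera called 13 of the 32 lists with its preset correlation, and with an estimated correlation it called 0, the lowest unadjusted p being 0.042 for the upper follicle list. By fry, which asks whether the genes of a list move one way on balance, 0 lists passed either, the lowest adjusted p being 0.096. Keeping only genes with a mean FPKM of at least 5 left 8 lists called by camera. The calls that ended included, but were not limited to, sterol and fatty acid synthesis (camera adjusted p = 0.057), interleukin-1 and NF-kB (camera adjusted p = 0.388) and Wnt (camera adjusted p = 0.515).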

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

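Alternatives on length, GC content, removal of ribosomal, mitochondrial and small RNAs, and edgeR with a filter of mean FPKM at least 1 were chosen after seeing the data. Of the 162 higher and 33 lower genes, 0 changed sign under any alternative that tested them. Because the diets did not overlap for any of these genes, leaving out a library could hardly reverse a sign, so this says little. Counts in both directions stayed within 1.5 times with median-of-ratios scaling, a filter of mean FPKM at least 5, either trend removed, and ribosomal, mitochondrial and small RNAs left out. Other settings moved a count by more. Higher and lower genes numbered 408 and 225 without a count filter, where more genes were tested, 90 and 3 with equal TPM sums, 106 and 9 without an abundance trend in the prior, 275 and 119 with DESeq2 and 280 and 101 at an adjusted p under 0.1. Lower genes numbered 55 with mean FPKM at least 1, 60 with a robust prior and 4 with an absolute log2 fold change of at least 1. Limma on log2(FPKM + 1), log2(FPKM + 0.1) or log2(FPKM + 0.01) called 1 higher and 0 lower gene each time, with 1793, 1779 and 1768 at an unadjusted p under 0.05. It called 0 and 0 without a trend (1524 unadjusted), and 3 and 2 after quantile normalization. Limma recovered fewer simulated changes than edgeR, but with 72 calls against 138 there, this does not account for its 1 call here. No simulated gene varied beyond the trend with abundance, unlike some genes here. The cause of these shifts was not tested. With each library left out in turn, higher genes numbered 0 to 81 and lower genes 0 to 2, with 1 library in a diet, and lists 11 to 16. Without the first normal diet library, which gave the 0, 1488 genes had an unadjusted p under 0.05. Camera called 8 lists, not 13, with mean FPKM at least 5, and 0 with an estimated correlation, as did fry with 0. Every other alternative that tested lists gave between 11 and 16.

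Over all genes named here and alternatives, 1077 values kept their direction and side of the threshold, 532 kept their direction but lost the call and 25 gained one. Log2 fold changes of 4 uncalled genes changed sign when a library was left out, ranging from -0.60 to 0.086 for Mki67, from -0.17 to 0.021 for Plin2, from -1.10 to 0.28 for Hmox1 and from -0.18 to 0.39 for Il1r1, with -0.14 for Il1r1 without the second normal diet library.

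With the replicate number as a block, 308 genes were higher and 111 lower, and 16 lists were called. Deviations of libraries with the same number from their diet's mean had a correlation of -0.0046 over the genes tested, so nothing in the labels or these values shows that the numbers are paired. At this depth edgeR recovered 50% of simulated 2-fold changes, so changes of that size can be missed.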

Other observations

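Tests of granular markers, of bulge markers and of other RNAs without a poly(A) tail, with their minimum of 5 CPM where one is given, and the terms and histone family described next, were chosen after the results were seen. Among the 162 higher genes, 2 of 1247 biological process terms were enriched (one-sided Fisher's exact test). Keratinization held 4 of its 14 tested genes (adjusted p = 0.026), namely Abca12, a lipid transporter of the cornified layer, Evpl and Ppl, which encode cornified envelope scaffolds, and Krt2. Positive regulation of T cell mediated cytotoxicity held 4 of 17 (adjusted p = 0.030), the class I genes H2-D1, H2-K1 and H2-Q7 and their partner B2m. Similar sequences leave the separate values of the class I genes uncertain. Summed over H2-D1, H2-K1 and B2m, expression was 645 CPM with the normal diet and 1064 CPM with the high-fat diet, and summed over 23 T cell and myeloid markers it was 80.7 and 135 CPM.

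Among the 33 lower genes, nucleosome assembly held 6 of its 72 tested genes (adjusted p = 6.37e-06). Of 60 measured replication-dependent histone genes, 14 were lower and 0 higher, and 60 had negative log2 fold changes with a median of -0.76. On quantile-normalized FPKM, which moved the median to -0.66, 58 of 58 were negative. With each library left out in turn the median lay between -0.99, without the second normal diet library, and -0.47, without the first, and between 57 and 60 of the 60 genes were negative. Many of these genes are near-identical copies, so their number is not a number of independent measurements.

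The 162 genes higher with the high-fat diet were weighed against trends in the libraries and against chance. After removal of a smooth trend on exonic length 161 of the 162 were still called higher, and after removal of a trend on GC content 162 were, which argues against either trend as the whole cause. The 4 libraries allow 3 splits into pairs, too few for a share under 0.05, and 1 split, the real one, gave as many as 195 called genes, while the highest of the others gave 0. The diet and any unrecorded difference in day, isolation or library preparation stay open, and no value here separates them.

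Of 36 suprabasal epidermal genes 6 were higher and 1 lower with the high-fat diet, and the call of the list was lost with an estimated correlation (adjusted p = 0.44); a larger share of differentiating keratinocytes is a candidate explanation beside a change within the stem cells. A panel of 7 granular and cornified envelope markers with means of at least 5 CPM had a median log2 fold change of -0.024. Its standard error over genes taken as independent was 0.46, and Flg stood at -2.27 and Hrnr at -1.34. The panel leaves out other genes of the cornified envelope that went up. These include Evpl and Ppl, which were called higher, and Ivl at 0.89, which was not called. The panel's members go both ways, its error is wide and it is partial, so a larger share of granular cells is not excluded. Bulge markers had a median of -0.13 with a standard error of 0.11 over 32 genes taken as independent. This leaves a larger share of spinous or upper follicle keratinocytes open as well. Since the labels do not state how the cells were isolated, a changed mixture and a changed state of the cells cannot be told apart.

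Of 50 cell cycle genes 1 and of 60 histone genes 14 were lower with the high-fat diet, and the call of the cell cycle list was lost with an estimated correlation (adjusted p = 0.44). The explanations considered were fewer cycling cells with the diet, 1 normal diet library with more of them, and a lower yield of RNA without a poly(A) tail, which replication histone transcripts lack. Other RNAs without a poly(A) tail and with a mean of at least 5 CPM had a median log2 fold change of 0.072 over 7 genes. Each of the 7 lay between -0.057 and 0.67, against a median of -0.76 for histone genes, which argues against a lower yield. The standard error of the difference, 0.13, takes genes as independent, which histone copies are not, and does not measure spread between libraries. The median of the cell cycle list was -0.51 in all 4 libraries and -0.256 without the first normal diet library. The bound set in advance, a median under -0.25 whichever library is left out, was met, but narrowly without that library. The standard error of that median, 0.04 over genes taken as independent, does not measure spread between libraries. With so thin a margin, that library's part in the pattern and that of the diet cannot be told apart.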
